A study of Mus musculus with 4 samples.

How the data were processed

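Single-cell 3' RNA sequencing libraries were made from cells positively selected for CD11b, from colon lamina propria or colon SILT of wild-type or Csf2-/- mice, 1 library for each of the 4 groups. The series design text gives 5 mice, and whether their cells were pooled is not stated. The deposited matrices hold UMI counts per gene and barcode, whole numbers with no normalization, for 32285 features. Per the submitters' processing notes the reads were processed with Cell Ranger 2.1.1 against mm10, whereas per the file headers the matrices were written by version 6.0.0, and per the labels' protocols the libraries used version 2 chemistry. The versions disagree and could not be reconciled from the files. Barcodes had already been called by the authors, the lowest total per barcode being 500 to 502 UMIs. Uncalled barcodes were not used here, and free RNA was not subtracted. Samples were grouped by the genotype and tissue of the labels.

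Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept. Doublets were called per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.8% per 1000 cells and left out (59, 146, 7 and 10 cells in wild-type lamina propria, wild-type SILT, Csf2-/- lamina propria and Csf2-/- SILT). All 4 libraries were clustered together, without batch correction because library and group are the same thing, on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden algorithm (leidenalg 0.10.2, igraph 0.11.9) at resolution 1. A cluster was named when at least 3 fixed markers of 1 of 22 classes were at least 2-fold higher than in the other clusters and found in at least 10% of its cells, with rules against mixed clusters. Clusters that failed were left unnamed and are called by their number and leading genes.

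Counts of macrophage-like cells were summed per library and divided by the summed UMIs of the class and scaled to a fixed total (CPM), and monocyte-like and endothelial-like cells were summed the same way. Macrophage-like sums held 12213295 UMIs in wild-type lamina propria, 9885675 in wild-type SILT, 2974498 in Csf2-/- lamina propria and 4638630 in Csf2-/- SILT. Ratios were taken without a pseudocount. With 1 library per group no p-value was computed and cells were not used as replicates. Precision is given as exact Poisson, binomial and conditional binomial intervals at the 95% level with scipy 1.17.1, and a count of 0 as the limit that 3 counts would set. The comparisons were Csf2-/- against wild type in each tissue and SILT against lamina propria in each genotype. For 27 fixed gene lists, the median log2 ratio over members with a mean of at least 10 CPM was given with a binomial interval over members and its percentile among 10000 random lists of the same size matched in 20 expression bins.

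The named genes of a comparison were the 8 highest and 8 lowest by ratio among genes with at least 50 CPM in 1 of the libraries and at least 30 UMIs over both, the 2 members of each list with the largest ratio, and always Csf2, its receptor genes, Csf1r, Cx3cr1 and Ccr2. Mitochondrial, ribosomal, immunoglobulin, T cell receptor, haemoglobin, sex-linked reference and unnamed genes and markers of other classes were left out of the highest and lowest. Of the list members only those that illustrate a list are printed. The lists, markers, naming rule, filters and the first set of other settings were fixed before the data were examined. Values within clusters 2 and 7, the Il22ra2 and Retnla clusters, the dendritic cell genes and the tests of explanations were chosen after seeing the data. Genes whose reads can map to paralogs (Bcl2a1b, Csf2rb, Lyz1) are given as uncertain. Coordinates are from GENCODE M21 on GRCm38.

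That first set was other cell filters, keeping doublets, other Leiden resolutions, clustering without list genes, clustering each library alone, thinning cells to 1000 UMIs, TMM factors (edgeR 4.0.16 in R 4.3.3), CPM without mitochondrial and ribosomal genes, means over cells, other list floors, a gate on 2 C1q UMIs, and both myeloid classes together. Counting intervals and list percentiles were tested on simulated data with the depths of the 4 libraries. The interval of a 2-fold difference lay clear of 1 for 97.0% to 100% of simulated genes, that of a 1.5-fold difference for 77.6% to 97.0%, and that of an unchanged gene for 4.3% to 5.0%. The simulated counts were drawn as Poisson counts, as the intervals assume, so these figures check the computation and not the assumption. UMIs that gather in a few cells were not simulated, and for such genes the intervals can be too narrow. The spread between mice is not covered either, and the design does not measure it. Further tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.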

Results

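Cells of the mouse colon that carry CD11b, an integrin of monocytes, macrophages, neutrophils and part of the dendritic cells, were profiled by droplet single-cell RNA sequencing of 3' ends. They came from the lamina propria, the connective tissue under the epithelium, or from solitary isolated lymphoid tissues (SILT), the small lymphoid aggregates of the gut wall. The mice either carried Csf2, which encodes the myeloid growth factor CSF2 (GM-CSF), or lacked it (Csf2-/-), and all had reporter alleles at Cx3cr1 and Ccr2. Whether these alleles change the counts of Cx3cr1 and Ccr2 was not examined, so the values of both genes are uncertain. Each of the 4 groups was 1 library, so no replicate error exists, no test across animals was possible, and every interval given is a 95% interval for counting error only (exact Poisson for a level, exact binomial for a share, exact conditional binomial for a ratio). The wild-type lamina propria library held 50017502 UMIs over 5128 barcodes and the Csf2-/- lamina propria library 19225644 over 2158. The wild-type SILT library held 67656927 UMIs over 8041 barcodes and the Csf2-/- SILT library 21225800 over 2578. After filtering, 4432, 1967, 7568 and 2368 cells remained in the same order, with medians of 9969, 8892, 5815.5 and 7184 UMIs per cell. Xist and the Y-linked Ddx3y were both present in every library, at 392 and 58.4 CPM (UMIs of a gene scaled to a fixed total per library) in wild-type lamina propria, 825 and 28.1 in Csf2-/- lamina propria, 266 and 38.4 in wild-type SILT and 582 and 31.8 in Csf2-/- SILT, so both sexes contributed in unequal mixes. In each tissue Xist was higher and Ddx3y lower in Csf2-/- than in wild type. The genotype comparisons below therefore cannot separate genotype from a difference in the mix of sexes.

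Clustering of all 4 libraries gave 31 clusters. Macrophage-like cells formed cluster 2, led by Lyve1, Folr2, Cd163 and F13a1, and cluster 7, led by Mmp13, H2-M2, Apol7c and Ms4a7. Monocyte-like cells formed cluster 3, led by Ccr2, Il1b and Ms4a4c, and cluster 13, led by Chil3, Hp and Plac8. The names were rebuilt here from fixed marker lists and are not the study's own. The wild-type and Csf2-/- lamina propria libraries held 926 and 286 macrophage-like cells, and the wild-type and Csf2-/- SILT libraries 963 and 402. Endothelial-like cells, which should not carry CD11b, made up 15.6% of wild-type and 10.7% of Csf2-/- lamina propria cells and 13.7% of wild-type and 10.1% of Csf2-/- SILT cells. They served as the reference for differences shared by a whole library and for free RNA.

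Csf2 itself (ENSMUSG00000018916, minus strand of chromosome 11 from 54247271 to 54249667 in GRCm38) was read first, because the genotype labels rest on it. Wild-type SILT held 24 Csf2 UMIs (0.372 CPM, 0.238 to 0.554) in 11 cells, and Csf2-/- SILT held 0, which allows up to 0.145 CPM. Of the 24 UMIs, 22 lay in cluster 18, a mix of T and NK or ILC1-like cells led by Gzma, Ccl5, Nkg7 and Trbc2 that held 142 cells in that library. In Csf2-/- SILT the cluster held 42 cells. The intervals take UMIs as independent, but the 24 UMIs gathered in 11 cells. The 0 UMIs of Csf2-/- SILT therefore do not settle a loss of Csf2 there. Wild-type lamina propria held 2 UMIs (0.0415 CPM, 0.0050 to 0.150) and Csf2-/- lamina propria 0, which allows up to 0.16 CPM, so a loss of Csf2 was not detectable at this depth in lamina propria. The deleted part of the gene is not described in the labels, and a 3' tag outside it would carry no information on the genotype.

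The comparison of Csf2-/- with wild-type SILT asks how monocytes and macrophages of the lymphoid aggregates differ when CSF2 is missing. Macrophage-like cells of Csf2-/- SILT held 219.9 CPM of Cxcr4, the receptor of the chemokine CXCL12, against 78.9 CPM in wild type, 2.79-fold higher (2.54 to 3.06). Grk3, a kinase that desensitises G protein-coupled receptors, was 2.74-fold higher (2.41 to 3.11), Cxcl10, an interferon-inducible chemokine, 2.75-fold higher (2.35 to 3.23), and Itgal, the alpha chain of the integrin LFA-1, 2.36-fold higher (1.98 to 2.81). The 359 Cxcl10 UMIs of Csf2-/- SILT lay in 38 cells, with 98 in 1 of them. Without the highest cell of each library Cxcl10 was 2.46-fold higher. Tlr8, which encodes an endosomal Toll-like receptor, was 2.29-fold lower in Csf2-/- SILT (1.86 to 2.85), at 22.9 against 52.4 CPM. Itgal leads the monocyte-like cluster 13, so monocyte-like cells among the macrophage-like cells are not excluded for it. For Grk3, Cxcl10, Cxcr4 and Tlr8 the directions held inside the clusters. Within cluster 2, cluster 7 and monocyte-like cells the log2 ratios of Grk3 were 1.29, 1.23 and 1.25, those of Cxcl10 1.07, 1.10 and 1.80, those of Cxcr4 0.57, 1.38 and 1.16, and those of Tlr8 -1.14, -0.97 and -1.31. Among the cells, monocyte-like cells were 54.1% (50.7 to 57.5) of the monocyte-like and macrophage-like cells of Csf2-/- SILT and 36.4% (34.0 to 38.9) of those of wild-type SILT.

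Further genes with higher levels in Csf2-/- SILT macrophage-like cells were Plac8, 4.16-fold (3.55 to 4.88), and the nuclear receptor gene Nr4a1, 2.44-fold (2.06 to 2.89). The Plac8 ratio lay in cluster 7 (log2 2.31) and was close to 0 in cluster 2 (log2 0.098). Plac8 leads the monocyte-like cluster 13, and in cluster 7 the monocyte list had a median of 0.32 (-0.044 to 2.30) with 5 of 12 members at least 1.5-fold higher, so monocyte-like cells within cluster 7 are not excluded. Kdm6b, a histone H3K27 demethylase gene, was 2.29-fold higher (2.0 to 2.62), but endothelial-like cells also held more of it (131.9 against 58.5 CPM). Ccl8, a monocyte-attracting chemokine, was 2.18-fold lower (2.0 to 2.38), Plau, which encodes urokinase, 2.14-fold lower (1.82 to 2.52) and Vps13c 2.14-fold lower (1.87 to 2.45). Fabp4 and Igfbp7 were 2.98-fold and 2.66-fold lower, at 20.3 and 23.1 CPM in Csf2-/- macrophage-like cells. Endothelial-like cells of Csf2-/- SILT held 7063 and 7821 CPM of them, so the macrophage values are read as background. AY036118 and Hist1h1e were 2.71-fold and 2.49-fold lower, and were lower in endothelial-like cells as well (244 against 572 CPM and 35.6 against 131.0 CPM). Cxcl9 was 2.74-fold higher in the sum, but 1 cell carried 272 of its 336 UMIs in Csf2-/- SILT. Without the highest cell of each library Cxcl9 was 1.62-fold lower in Csf2-/- SILT.

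The receptor genes of CSF2 were higher in Csf2-/- SILT macrophage-like cells: Csf2ra (ENSMUSG00000059326, chromosome 19) 1.51-fold (1.36 to 1.66) and Csf2rb (ENSMUSG00000071713, chromosome 15) 1.40-fold (1.26 to 1.55), the latter uncertain because its reads can be shared with its paralog Csf2rb2. The list of the CSF2 receptor and response genes had a median log2 ratio of 0.24 over 14 measured members (interval over members -0.36 to 0.59), with 3 members at least 1.5-fold higher and 1 at least 1.5-fold lower, and a percentile of 98.1 among random lists matched on expression. Endothelial-like cells had the same median, 0.25 over 10 measured members, so it is not read as a macrophage difference. Its members Pim1, a kinase gene induced by cytokines, and Id2, a transcriptional regulator, were 2.04-fold (1.86 to 2.24) and 1.83-fold (1.59 to 2.11) higher, and endothelial-like cells also held more Pim1 (65.7 against 32.3 CPM). All 13 genes of the CSF1 axis and resident macrophage regulators had ratios above 1, with a median log2 ratio of 0.28 (0.084 to 0.80, percentile 99.8). Among them Cebpa, a myeloid transcription factor gene, was 1.91-fold higher (1.74 to 2.1) and Csf1r, the CSF1 receptor gene, 1.14-fold higher (1.11 to 1.18). Cx3cr1, the fractalkine receptor gene, was 1.35-fold higher (1.29 to 1.42), whereas the interval of Ccr2, the monocyte chemokine receptor gene, included 1 (ratio 1.07, 0.938 to 1.21). Cluster 7 held 221 of 402 macrophage-like cells in Csf2-/- and 366 of 963 in wild-type SILT. In wild-type SILT it held 134.7 CPM of Csf2rb, against 60.1 CPM in cluster 2. No values within the clusters are given here for Csf2ra, Csf2rb, Pim1, Id2, Cebpa and Cx3cr1, so that balance is not excluded for them.

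The 10 genes of MHC class II presentation had a median log2 ratio of 0.38 in Csf2-/- SILT macrophage-like cells (0.14 to 0.56, percentile 99.9), with 9 above 0 and 1 at least 1.5-fold higher. Ciita, the class II transactivator gene, was 1.53-fold (1.38 to 1.70) and H2-Ab1 1.48-fold (1.46 to 1.5) higher. The list median was 0.25 within cluster 2 and 0.063 within cluster 7, and 0.11 with both clusters at equal weight. Axl, a receptor for apoptotic cells, was 1.79-fold higher (1.65 to 1.94), Slc11a1, a phagosomal metal transporter gene, 1.61-fold higher (1.45 to 1.77) and P2rx7, an ATP-gated channel gene, 1.43-fold higher (1.27 to 1.61). In wild-type SILT cluster 7 held 8416 CPM of H2-Ab1 and cluster 2 held 932.5 CPM. The balance of the clusters is not excluded for Ciita, H2-Ab1, Axl, Slc11a1 and P2rx7, which have no values within the clusters here. Selenop was 1.51-fold lower (1.48 to 1.54), but its log2 ratio was 0.077 when cells were taken by their C1q counts instead of clusters. Lyz1 was 1.65-fold lower (1.43 to 1.92), uncertain because Lyz1 and Lyz2 share sequence. The list of regulatory genes had a median of 0.32 (0.18 to 0.47, percentile 99.03), with all 10 measured members above 0, but 0.17 within cluster 2, 0.16 within cluster 7 and 0.40 in endothelial-like cells, and the list of chemokines had 0.29 (-0.29 to 0.58, percentile 99.9). The long-lived gut macrophage list was at -0.22 (-0.68 to 0.096, percentile 1.24) in the sum, but at 0.046 within cluster 2, 0.41 within cluster 7 and 0.074 with both at equal weight, and holds genes that lead cluster 2. Nuclear genes of respiratory complex I had a median of -0.11 (-0.17 to -0.050, percentile 2.98), and -0.082 in endothelial-like cells. The other lists lay between -0.36 (cell cycle, 3 measured members) and 0.26 (monocyte genes). In monocyte-like cells of Csf2-/- SILT the resident macrophage core genes were lower (median log2 ratio -0.30, -0.66 to -0.051, 14 of 18 below 0). Endothelial-like cells had this list at -0.20 (-1.02 to 0.52) over 10 measured members, so a lower background of macrophage RNA is not excluded.

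Monocyte-like and macrophage-like cells together were 37.0% (35.0 to 39.0) of Csf2-/- SILT cells and 20.02% (19.1 to 20.9) of wild-type SILT cells. Shares describe the cells that passed the CD11b selection, and the libraries differed in depth. They also differed in other cells. Of 7568 wild-type and 2368 Csf2-/- SILT cells, 550 and 97 were B cell-like and 125 and 0 epithelial-like. Fibroblast-like cluster 16 held 217 and 24, whereas cluster 8, led by haemoglobin genes, held 253 and 179. A difference in what the preparations held is therefore not excluded as a source of the myeloid share. Clustered without the leading genes of these clusters, the monocyte-like share among both classes was 44.1% (40.7 to 47.6) against 24.2% (21.95 to 26.5). With each library clustered on its own the order turned, to 22.7% in Csf2-/- and 37.7% in wild-type SILT. A further group, clusters 6 and 22, was led by Il22ra2, which encodes the soluble IL-22 binding protein, together with Cst7, Lyz1, Acp5 and Pla2g2d, and kept no class name. These Il22ra2 clusters were 14.6% (13.8 to 15.4) of wild-type SILT cells and 6.33% (5.39 to 7.39) of Csf2-/- SILT cells, and 15.1% against 6.88% when clustered without their leading genes. Their cells were shallow, with medians of 1075 and 1631 UMIs in clusters 6 and 22, or 0.181 and 0.277 of the median of their own library. Among cells with at least 2000 UMIs the shares were 3.26% and 1.16%. After thinning every cell to 500 UMIs, 8.79% of wild-type and 4.43% of Csf2-/- SILT cells held an Il22ra2 UMI, against 0.290% and 0% of endothelial-like cells. Cluster 24, led by Retnla, Lpl and Fn1, was 0.555% (0.400 to 0.749) of wild-type and 0.0845% (0.0102 to 0.305, 2 cells) of Csf2-/- SILT cells, or 0.529% (0.378 to 0.719) against 0.211% (0.0686 to 0.492), with overlapping intervals, when clustered without its leading genes.

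**Figure D1:**
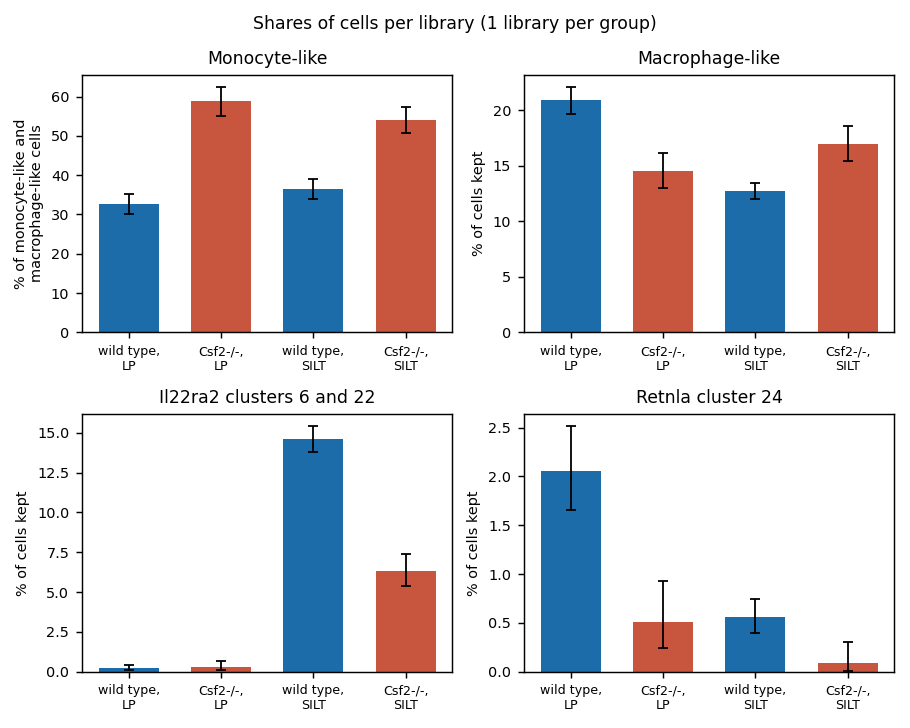
Shares of cells in each of the 4 libraries, in percent of the cells named on each vertical axis (LP, lamina propria), with 1 library per bar and exact binomial 95% intervals. Monocyte-like cells were 54.1% and 58.8% of the monocyte-like and macrophage-like cells in the Csf2-/- libraries and 36.4% and 32.7% in the wild-type libraries.

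The comparison of Csf2-/- with wild-type lamina propria asks the same of the diffuse tissue. Cxcr4 was again higher in macrophage-like cells, 3.08-fold (2.74 to 3.48), at 163 against 53.0 CPM, and Tlr8 again lower, 3.35-fold (2.58 to 4.42). The chemokine genes Cxcl1, Ccl4 and Ccl12 were 5.86-fold (4.72 to 7.30), 4.83-fold (4.20 to 5.55) and 3.03-fold (2.56 to 3.58) higher in Csf2-/- lamina propria. The Csf2-/- UMIs of Cxcl1 lay in 31 cells. For Ccl12 1 cell held 56 of the 247 Csf2-/- UMIs, and without the highest cell of each library it was 2.57-fold higher. The list of dissociation and heat-shock genes, a sign of handling, was at 0.38 (0.036 to 0.56) in endothelial-like cells of the same comparison, at 0.16 (-0.038 to 0.29) in macrophage-like cells and at 0.031 and -0.070 within clusters 2 and 7. Abca9, an ABC transporter gene, was 2.33-fold (2.12 to 2.56), Eps8, an actin regulator gene, 2.22-fold (1.99 to 2.48) and Colec12, a scavenger receptor gene, 2.43-fold (2.13 to 2.80) lower. Each of the 8 genes named here had the same direction in cluster 2 and in cluster 7, with log2 ratios of 0.81 and 1.11 for Cxcr4, 1.33 and 2.50 for Cxcl1, -1.71 and -1.26 for Tlr8 and -0.82 and -1.12 for Abca9. Monocyte-like cells were 58.8% (55.0 to 62.5) of the monocyte-like and macrophage-like cells in Csf2-/- and 32.7% (30.2 to 35.2) in wild-type lamina propria.

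Part of the macrophage difference in lamina propria went with the balance of the macrophage clusters. Cluster 7 was 36.0% (30.5 to 41.9) of macrophage-like cells in Csf2-/- and 11.8% (9.77 to 14.02) in wild-type lamina propria, or 43.8% against 18.4% when clustered without the leading genes. The 10 genes of MHC class II presentation had a median log2 ratio of 1.22 (0.73 to 1.54, percentile 100), with 9 of them at least 1.5-fold higher in Csf2-/-, H2-Eb1 2.99-fold (2.93 to 3.05) and H2-Ab1 2.92-fold (2.86 to 2.97). The median was 0.45 within cluster 2, 0.28 within cluster 7 and 0.32 with both at equal weight. Lag3, best known as an inhibitory receptor of T cells, was 7.42-fold higher (5.99 to 9.23) with a log2 ratio of 1.68 in cluster 7 and of -0.0011 in cluster 2. Cd9, a tetraspanin gene, and Cd72 were 3.73-fold (3.43 to 4.04) and 3.10-fold (2.70 to 3.56) higher, and both were higher within cluster 2 (log2 1.5 and 1.15) and within cluster 7 (0.68 and 0.47). Itgax, which encodes CD11c, was 2.69-fold higher (2.37 to 3.04) in the sum but had a log2 ratio of -0.0030 in cluster 7. H2-M2, Mmp13, Lyve1, Cd163 and Mrc1 lead cluster 7 or cluster 2 and follow that balance, so they are not read as separate differences.

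The inflammatory cytokine gene Il1b was 2.83-fold (2.60 to 3.07) and Lgals3, which encodes galectin-3, 2.31-fold (2.22 to 2.41) higher in Csf2-/- lamina propria macrophage-like cells. The list of inflammatory cytokines had a median log2 ratio of 0.67 (-0.11 to 1.99, percentile 100), with 4 of 7 members at least 1.5-fold higher, and fell to -0.010 within cluster 2 and 0.25 within cluster 7. The CSF2 receptor and response list was at 0.64 (-0.37 to 1.24, percentile 100), with 9 of 14 members at least 1.5-fold higher and 2 at least 1.5-fold lower, but at 0.012 within cluster 2 and 0.034 within cluster 7, so its value in the sum went with the balance of the clusters. In monocyte-like cells the same list was at -0.25 (-0.52 to 0.38, percentile 0.54) in lamina propria and at 0.0012 (-0.28 to 0.41) in SILT. Bcl2a1b, a survival gene with near-identical paralogs and therefore uncertain, was 2.31-fold higher (2.11 to 2.52) in macrophage-like cells. Csf2ra was 1.60-fold (1.43 to 1.78) and Csf2rb 1.34-fold (1.20 to 1.5) higher, Csf2rb with a log2 ratio of -0.084 in cluster 7. Axl was 2.19-fold higher (2.0 to 2.41), Cx3cr1 1.47-fold higher (1.39 to 1.55) and Csf1r 1.23-fold lower (1.19 to 1.27). Ccr2 was 1.43-fold higher (1.22 to 1.66) in the sum and lower within both clusters (log2 -0.20 and -0.39). P2ry12, an ADP receptor gene, was 1.78-fold lower (1.58 to 2.0). Regulatory genes had a median of 0.58 (0.058 to 1.28) with all 10 measured members above 0, but 0.19 within cluster 2 and 0.085 within cluster 7. Lipid handling genes had 0.44 (-0.21 to 1.18), with 0.080 and 0.13 within the clusters, so both lists went with the balance of the clusters. Matrix remodelling genes had 0.43 (0.038 to 1.49). The matrix list turned to -0.17 in cells taken by C1q counts and to -0.18 in monocyte-like and macrophage-like cells together. The long-lived gut macrophage list was at -0.40 (-1.03 to -0.013, percentile 0.330) in the sum and at 0.055 with both clusters at equal weight. Nuclear complex I genes had a median of 0.21 (0.15 to 0.25, percentile 100), and 0.22 in endothelial-like cells. The type I interferon response list was at 0.20 (-0.48 to 0.75) in the sum, which joins 0.64 (-0.40 to 0.95) in cluster 2 and -0.65 (-1.17 to 0.41) in cluster 7. The other lists lay between -0.28 (efferocytosis) and 0.39 (CSF1 axis, with 0.092 within cluster 2 and 0.099 within cluster 7).

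Lars2, a mitochondrial leucyl-tRNA synthetase gene, was 3.85-fold lower (3.56 to 4.16) in Csf2-/- lamina propria macrophage-like cells, and endothelial-like cells held less of it too (323 against 841 CPM). Syne2 and Utrn were 2.76-fold and 2.52-fold lower, with lower endothelial-like levels as well (419.7 against 656 CPM and 522 against 810.1 CPM). Retnla, a secreted product of alternatively activated macrophages, was 3.16-fold lower (2.80 to 3.59), with 1 cell holding 500 of the 3585 wild-type UMIs, and endothelial-like cells held less of it too (0.953 against 15.9 CPM). Within cluster 2 Retnla was 1.92-fold lower (1.69 to 2.18), and within cluster 7 it was 46.3-fold lower (19.7 to 144), at 5 against 339 UMIs. The 276 Retnla UMIs of Csf2-/- macrophage-like cells lay in 19 cells, with 96 in 1 of them, so these ratios rest on few cells. The Retnla cluster 24 was 2.05% (1.66 to 2.52) of wild-type and 0.508% (0.244 to 0.933) of Csf2-/- lamina propria cells, or 1.60% against 0.356% when clustered without its leading genes. Monocyte-like and macrophage-like cells together were 35.3% (33.2 to 37.4) of Csf2-/- and 31.0% (29.7 to 32.4) of wild-type cells, and this order turned in 3 of 12 other clusterings or filters: with every deposited barcode (21.3% against 21.5%) and when clustered without the leading genes of the Il22ra2 clusters (20.6% against 23.6%) or of the Retnla cluster (20.7% against 23.8%).

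**Figure D2:**
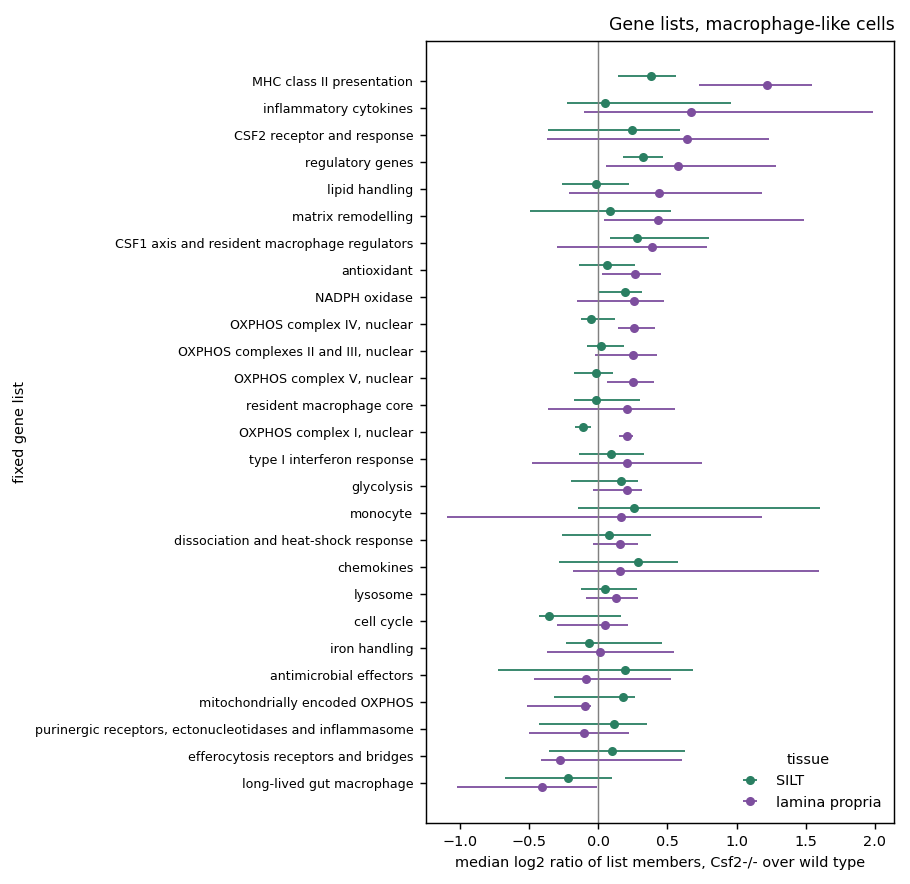
Median log2 ratio of Csf2-/- over wild type for each of the 27 gene lists in macrophage-like cells (horizontal axis), for SILT and lamina propria separately. Points are medians over the measured list members and lines are 95% binomial intervals over members; MHC class II presentation stood highest, at 0.38 in SILT and 1.22 in lamina propria.

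The comparison of SILT with lamina propria in wild type asks how macrophages of lymphoid aggregates differ from those around them. Macrophage-like cells of SILT held 4.61-fold more Acp5 (4.21 to 5.06), the gene of tartrate-resistant acid phosphatase, 3.77-fold more Gstp1 (3.21 to 4.43), a glutathione transferase gene, and 3.60-fold more Jaml (3.25 to 3.99), a leukocyte adhesion molecule gene. The chemokine gene Ccl9 was 2.59-fold (2.45 to 2.74) and the complement gene C4b 3.06-fold (2.69 to 3.48) lower in SILT. All of these kept their direction within clusters 2 and 7, with log2 ratios of 1.80 and 0.75 for Acp5 and of -0.89 and -1.25 for Ccl9, though endothelial-like cells also held more Gstp1 (104 against 53.3 CPM). Acp5 also leads the Il22ra2 clusters, which held 2021 CPM of it in wild-type SILT, so free RNA from them is not excluded. The 10 MHC class II presentation genes had a median log2 ratio of 1.35 (0.83 to 1.70, percentile 100), led by H2-DMb2 at 3.32-fold (2.82 to 3.92) and Cd74, the invariant chain gene, at 3.25-fold (3.22 to 3.28). Cluster 7, which was 38.0% (34.9 to 41.2) of macrophage-like cells in SILT and 11.8% in lamina propria, went with that value, and the median was 0.25 within cluster 2, 0.056 within cluster 7 and 0.62 over 5 measured members in endothelial-like cells.

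The 16 measured chemokine genes had a median of 0.74 (-0.023 to 1.34, percentile 100) with 10 at least 1.5-fold higher in wild-type SILT, while the matrix remodelling list was at 1.11 (-0.58 to 1.66) in the sum but at -0.14 within cluster 2 and -0.22 within cluster 7. Il1b was 3.71-fold higher (3.49 to 3.94), with log2 ratios of 0.032 in cluster 2 and 0.45 in cluster 7. Ccl4 was 4.01-fold higher (3.57 to 4.51), with -0.088 in cluster 2 and 1.05 in cluster 7. Bcl2a1b was 3.22-fold higher (3.03 to 3.43) and Gngt2 3.61-fold higher (3.29 to 3.97). H2-M2, Gbp2b, Mmp13 and Cd163 are leading genes of the macrophage clusters and are left aside here. Csf1r was 1.63-fold lower in SILT (1.59 to 1.66), Colec12 2.24-fold lower (2.07 to 2.42) and P2rx7 1.79-fold lower (1.63 to 1.96), while the intervals of Csf2ra and Csf2rb included 1 (ratio 1.0, 0.917 to 1.09, and 1.06-fold lower, 0.974 to 1.15). Within cluster 2 and within cluster 7 Csf2ra was lower in SILT (log2 -0.55 and -0.37). Cx3cr1 and Ccr2 were 1.06-fold (1.02 to 1.10) and 1.35-fold (1.21 to 1.5) higher in the sum and lower within both clusters.

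Nuclear genes of the respiratory chain stood higher in wild-type SILT and the genes of the mitochondrial genome lower. Complex I had a median log2 ratio of 0.59 (0.50 to 0.65) with 19 of 37 genes at least 1.5-fold higher, Ndufc2 2.0-fold (1.88 to 2.14), complex IV 0.56 with Cox5a 2.06-fold higher (1.96 to 2.16), complexes II and III 0.49 and complex V 0.47. The 13 mitochondrially encoded genes had a median of -0.59 (-1.39 to -0.28), with 7 at least 1.5-fold lower, mt-Atp8 4.29-fold (3.95 to 4.65) and mt-Nd3 3.24-fold (3.12 to 3.37). Endothelial-like cells had medians of 0.46 for complex I and -0.40 for the mitochondrially encoded genes, so cells outside the macrophage class shared both differences. The non-coding RNAs Neat1 and Mir99ahg were 3.40-fold (3.23 to 3.59) and 2.83-fold (2.54 to 3.16) lower in SILT, Plec, the gene of the linker protein plectin, 2.76-fold (2.54 to 3.0) and Nacc2 2.62-fold (2.28 to 3.01). Neat1 and Plec were also lower in endothelial-like cells (89.3 against 216 CPM and 270.4 against 415 CPM). Lars2 was 3.38-fold lower, with 255 against 841 CPM in endothelial-like cells, and Retnla 2.77-fold lower (2.59 to 2.97), with 6.26 against 15.9 CPM in endothelial-like cells. The median over all 7964 measured genes was -0.23 here, and scaling with TMM factors shifted every log2 ratio of this comparison by 0.19. The other lists lay between -0.38 (efferocytosis and long-lived genes) and 0.37 (type I interferon response).

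The comparison of SILT with lamina propria in Csf2-/- mice asks how the tissues differ without CSF2. Cxcl10 was 4.90-fold (3.61 to 6.79) and Plac8 5.29-fold (4.01 to 7.09) higher in SILT macrophage-like cells, Plac8 in cluster 7 (log2 3.25), where the monocyte list was at 0.45 (-0.10 to 2.75), and not in cluster 2 (log2 -0.065). The lamina propria value of Cxcl10 rests on 47 UMIs in 13 cells. Pla2g2d, a secreted phospholipase gene, was 2.57-fold (2.0 to 3.32), Napsa, an aspartic protease gene, 2.19-fold (1.70 to 2.84), Ccrl2, a chemerin-binding receptor gene, 1.87-fold (1.55 to 2.27) and Tnfaip2 1.86-fold (1.65 to 2.08) higher. For Pla2g2d 1 cell held 123 of the 320 SILT UMIs, and without the highest cell of each library it was 2.14-fold higher. Pla2g2d also leads the Il22ra2 clusters, so free RNA from them is not excluded for it. Acp5 was again higher, 1.83-fold (1.63 to 2.05), and C4b again lower, 4.29-fold (3.36 to 5.54). Lpl, the lipoprotein lipase gene, was 2.24-fold lower in SILT (1.86 to 2.70), Hspa1b, a heat-shock gene, 1.82-fold (1.71 to 1.93), Slmap 1.83-fold (1.44 to 2.32) and Gstm1 1.76-fold (1.47 to 2.1). The dissociation and heat-shock list was lower in SILT in endothelial-like (-0.14), monocyte-like (-0.39) and type 2 dendritic cell-like cells (-0.47) as well, and at -0.065 in macrophage-like cells, so a difference in handling is not excluded for Hspa1b, of which endothelial-like cells held 372 against 350 CPM.

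MHC class II presentation genes had a median log2 ratio of 0.34 in this comparison (0.083 to 0.78, percentile 100), with H2-DMb1 1.58-fold (1.48 to 1.69) and Cd74 1.46-fold (1.44 to 1.48) higher. The median was 0.50 over 5 measured members in endothelial-like cells and -0.028 with the macrophage clusters at equal weight, and cluster 7 was 55.0% (49.97 to 59.9) of macrophage-like cells in SILT and 36.0% in lamina propria. Complex I genes had a median of 0.23 (0.19 to 0.29), with 0.18 in endothelial-like cells, and mitochondrially encoded genes -0.38 (-0.62 to -0.058), with mt-Nd3 2.1-fold lower (1.97 to 2.24) and a median of -0.38 in endothelial-like cells as well. The type I interferon response list was at 0.37 (-0.21 to 0.65, percentile 100), with -0.026 within cluster 2 and 0.91 within cluster 7, where the list was low in Csf2-/- lamina propria. Csf1r was 1.15-fold lower in SILT (1.11 to 1.20), and the intervals of Csf2ra, Csf2rb, Cx3cr1 and Ccr2 included 1. Gda and Rgs18 were 2.31-fold and 1.81-fold lower in the sum and not lower within cluster 7 (log2 0.00125 and 0.48). AY036118 was 3.44-fold lower, as in endothelial-like cells (244 against 980.0 CPM). Cxcl9 was 9.37-fold higher, or 3.73-fold without the highest cell of each library. The Il22ra2 clusters were 0.248% of wild-type and 0.305% of Csf2-/- lamina propria cells, far below their shares in SILT. The other lists lay between -0.31 (cell cycle, 3 measured members) and 0.28 (complex IV).

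**Figure D3:**
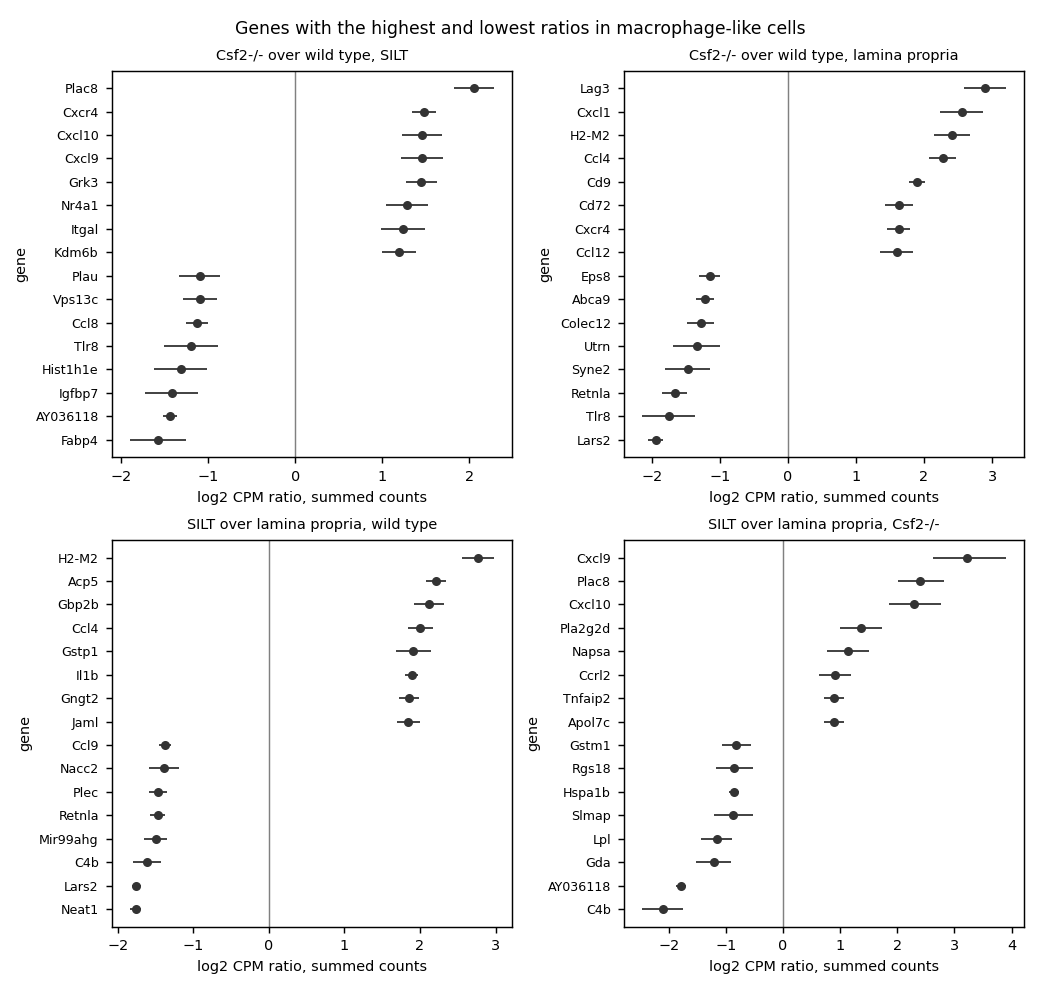
Log2 ratios (horizontal axes) of the 8 highest and 8 lowest genes of each of the 4 comparisons in the summed counts of macrophage-like cells. Points are ratios of CPM and lines are exact conditional binomial 95% intervals for counting error; Cxcr4 stood among the highest and Tlr8 among the lowest in both genotype comparisons.

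Set side by side, the genotype ratios of the tissues were close for some genes and apart for others, and the difference between tissues was given as a value without a test. The log2 ratio of Cxcr4 was 1.48 in SILT and 1.63 in lamina propria, that of Nr4a1 1.29 and 1.37, that of Csf2ra 0.59 and 0.68, and that of Tlr8 -1.20 and -1.74. Cxcl10 stood at 1.46 in SILT and 0.038 in lamina propria, a difference of 1.42. Il1b stood at -0.14 and 1.5, Ccl4 at 0.24 and 2.27, Lag3 at 0.88 and 2.89 and Cxcl1 at 0.87 and 2.55. The MHC class II list stood at 0.38 and 1.22 in the sums, but at 0.25 and 0.45 within cluster 2 and at 0.063 and 0.28 within cluster 7. Its gap between the tissues was therefore smaller inside the clusters and went in part with their balance. Lag3 likewise differed in lamina propria within cluster 7 and not within cluster 2. The differences between tissues were not tested.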

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

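The tests of explanations in this part were chosen after the result was seen.

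Nuclear complex I genes stood out because the genotype difference had opposite signs in the tissues: the median log2 ratio of Csf2-/- over wild type in macrophage-like cells was -0.11 in SILT and 0.21 in lamina propria, a difference of -0.32 that was not tested across animals. Another mix of macrophage clusters 2 and 7 is argued against, since the median of the 37 members' differences was -0.33 (-0.40 to -0.27) within cluster 2 and -0.20 (-0.29 to -0.090) within cluster 7. Endothelial-like cells showed the same difference, -0.31 (-0.34 to -0.24) against -0.29 (-0.38 to -0.22) in macrophage-like cells, so a difference between whole libraries may account for it. A tissue-dependent effect of CSF2 on respiration stays open and untested.

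Cxcl9 had opposite signs in the tissues as well, with log2 ratios of 1.46 in SILT and -1.08 in lamina propria, a difference of 2.54 that was not tested and in which 1 cell held 272 of the 336 Csf2-/- SILT UMIs. Without the highest cell of each library the SILT value turned to -0.70, so the opposite signs rest on that cell. The share of macrophage-like cells was 4.25 percentage points higher in Csf2-/- than in wild-type SILT and differed by -6.35 points in lamina propria, a difference between tissues of 10.6 points that was not tested. That share leaves out the Il22ra2 clusters, which kept no class name. In wild-type SILT these clusters held C1qa and Apoe at 0.83 and 0.90 of the macrophage-like level, but Adgre1 and Mrc1 at 0.066 and 0.024. Their own share differed by -8.27 points between Csf2-/- and wild-type SILT, so the SILT sign depends on leaving them out.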

How the results depend on the processing

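Of the planned values of list medians, 1319 stayed inside the interval of the value reported, 73 moved outside it and 4 turned direction. Of those of named genes, 888 stayed, 446 moved and 8 turned, and of those of cell shares 32 stayed and 40 moved. Of the values from alternatives added after seeing the data, 276 list medians stayed, 42 moved and 6 turned, 195 gene values stayed, 269 moved and 22 turned, and 74 shares stayed and 46 moved. A value counts as turned only if the interval of the reported value lay clear of no difference. Changes of sign in values whose interval included no difference count as stayed or moved, and came to 146 list medians and 25 gene values among the planned values and 83 list medians and 10 gene values in the added ones. The monocyte-like share of monocyte-like and macrophage-like cells was higher in Csf2-/- than in wild-type lamina propria in 12 of 12 other clusterings or filters, and in SILT in 11 of 12. The Il22ra2 clusters held less of Csf2-/- than of wild-type SILT in 12 of 12, and the Retnla cluster less in both tissues in 12 of 12. No paired analysis was possible because the labels pair no libraries. Depth limited Csf2 in lamina propria, and the few cells that held it limited it in SILT. Without replicates no value has an error across animals. Except where its construction shows it, the cause of a move was not tested.

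The share of monocyte-like and macrophage-like cells among all cells is called the myeloid share here, and that of monocyte-like cells among both the monocyte share. With at least 500 genes the myeloid share was 34.2% in wild-type lamina propria, 22.9% in wild-type SILT and 43.7% in Csf2-/- SILT, and the monocyte share of Csf2-/- SILT 58.5%, fewer shallow cells being left. With at most 5% mitochondrial UMIs the monocyte share was 39.4% in wild-type lamina propria, 63.6% in Csf2-/- lamina propria and 58.2% in Csf2-/- SILT. With every deposited barcode the myeloid share was 21.5%, 16.0%, 21.3% and 30.5% in wild-type lamina propria, wild-type SILT, Csf2-/- lamina propria and Csf2-/- SILT, and the monocyte share 14.4%, 24.5%, 36.7% and 46.2% in the same order, which the next values keep. Thinned to 1000 UMIs the shares were 35.6%, 24.2%, 37.7% and 42.0%, and 22.8%, 30.5%, 49.2% and 49.4%. At resolution 0.5 the myeloid share was 33.7%, 22.9% and 42.0% in wild-type lamina propria, wild-type SILT and Csf2-/- SILT. At resolution 2 the shares were 21.1%, 8.60%, 22.5% and 23.7%, and 29.4%, 58.1%, 70.2% and 66.3%. Without list genes the myeloid share of Csf2-/- SILT was 34.9%, and the monocyte share 33.2% in wild-type SILT and 53.4% in Csf2-/- lamina propria. With each library on its own the myeloid share was 21.7% in wild-type lamina propria and 23.8% in Csf2-/- SILT, and the monocyte share of Csf2-/- SILT 22.7%. Without the leading genes of the monocyte-like and macrophage-like clusters the myeloid share was 18.9% in wild-type and 34.5% in Csf2-/- SILT, and the monocyte share 21.8%, 24.2%, 46.6% and 44.1%. Without those of the Il22ra2 clusters the shares were 23.6%, 15.3%, 20.6% and 25.5%, and 9.27%, 16.3%, 28.6% and 33.2%. Without those of the Retnla cluster they were 23.8%, 15.4%, 20.7% and 25.6%, and 9.49%, 17.2%, 29.2% and 34.2%. Cluster 3 met exactly 3 markers and dropped out of the monocyte-like class in some of these settings.

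Among list medians, the complex I value of Csf2-/- over wild type in SILT was -0.18 with TMM factors, -0.42 in cells taken by C1q counts and -0.0039 in cluster 2 alone, and that in lamina propria 0.11 by C1q counts, 0.30 in cluster 2 and 0.071 in cluster 7. The MHC class II median of the genotype ratio in SILT was 0.74 by C1q counts, 0.063 in cluster 7 and 0.11 at equal weight of the clusters. In lamina propria it was 0.45 in cluster 2, 0.28 in cluster 7, 0.32 at equal weight and 1.80 at resolution 2. For SILT over lamina propria in Csf2-/- it turned to -0.19 by C1q counts, -0.064 in cluster 7 and -0.028 at equal weight, and the monocyte list turned to -0.065 in cluster 2. For SILT over lamina propria in wild type, inflammatory cytokines turned to -0.34 by C1q counts. For the genotype ratio in lamina propria, matrix remodelling turned to -0.17 by C1q counts, -0.029 in cluster 7 and -0.18 in both classes together, and the long-lived list to 0.075 in cluster 2 and 0.055 at equal weight.

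Among named genes, Cxcl9 turned to a log2 ratio of -1.22 in cluster 7 and of -0.70 without the cell with the most UMIs, and Selenop to 0.077 by C1q counts, for the genotype ratio in SILT. For that in lamina propria Ccr2 turned to -0.20 in cluster 2, -0.39 in cluster 7, -0.36 at equal weight and -0.48 at resolution 2, Lag3 to -0.0011 and Mmp13 to -0.36 in cluster 2, Csf2rb to -0.084 in cluster 7 and -0.057 at equal weight, and Cx3cr1 to -0.12 and Itgax to -0.0030 in cluster 7. For SILT over lamina propria in wild type Ccr2 turned to -0.052 with at most 5% mitochondrial UMIs, -1.13 by C1q counts, -0.61 in cluster 2, -0.54 in cluster 7, -0.55 at equal weight and -0.19 in both classes together. Cx3cr1 turned to -0.053 in cells thinned to 1000 UMIs, -0.74 by C1q counts, -0.082 in cluster 2, -0.57 in cluster 7, -0.41 at equal weight and -0.19 in both classes together, and Ccl4 to -0.088 in cluster 2. For SILT over lamina propria in Csf2-/- Plac8 turned to -0.065 in cluster 2, and Gda to 0.00125, Lyve1 to 1.80 and Rgs18 to 0.48 in cluster 7.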

Other observations

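The tests of explanations in this part were chosen after the result was seen, except the shares taken by Retnla counts without clusters, and the genes and cells of the first paragraphs were picked from their values.

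Type 2 conventional dendritic cell-like cells (cluster 5) carried large genotype differences in both tissues, summed like the macrophages and leaving aside the genes that lead the cluster. Ear2, an eosinophil-associated ribonuclease gene, was at 6.0 CPM in Csf2-/- SILT against 105 in wild type, 17.4-fold lower (9.87 to 34.1), and 11.7-fold lower (7.80 to 18.2) in Csf2-/- lamina propria. Mmp12, the macrophage elastase gene, was 10.8-fold lower (6.82 to 18.2) in SILT and 15.2-fold lower (8.92 to 28.0) in lamina propria, and Pilra, an inhibitory receptor gene, 4.63-fold (2.96 to 7.57) and 8.64-fold (5.36 to 14.8) lower. Xlr and Mrc1, the mannose receptor gene, were 2.94-fold and 2.42-fold lower in SILT and 7.17-fold and 4.96-fold lower in lamina propria. Ear2 was seen in 100 of 341 wild-type SILT cells and in 11 of 205 Csf2-/- SILT cells, so no single cell carried its difference. For Mmp12 in SILT 1 wild-type cell held 84 of 355 UMIs and 1 Csf2-/- cell 13 of 19, and without the highest cell of each library it was 26.1-fold lower. Tpcn1, a lysosomal channel gene, was 2.51-fold (1.96 to 3.24) and 2.09-fold (1.77 to 2.49) higher in Csf2-/- SILT and lamina propria, Pou2f2 2.43-fold and 1.62-fold, Klra17 1.76-fold and 2.18-fold, and Dusp2, a phosphatase gene, 1.90-fold and 1.94-fold. Endothelial-like cells held at most 1.15 CPM of Pilra and 1.16 CPM of Ear2. They also held less Mrc1 in Csf2-/-, 4.63 against 9.32 CPM in SILT and 4.29 against 16.1 CPM in lamina propria. Their Xlr was at 5.55 against 7.92 CPM in SILT and 4.29 against 6.84 CPM in lamina propria. In Csf2-/- lamina propria the type 2 cells held 7.35 CPM of Xlr, close to that background. The CSF2 receptor and response list had a median log2 ratio of -0.21 (-0.88 to 0.27, percentile 1.05) in SILT type 2 cells. In those of lamina propria it was at -0.43 (-1.28 to 0.025, percentile 0). In each tissue 12 of 16 measured members lay below 0, while endothelial-like cells had medians of 0.25 and 0.26. Macrophage genes moved both ways in the type 2 cells. The resident macrophage core list had a median log2 ratio of -0.53 (-0.84 to 0.072) in SILT and -0.40 (-0.69 to 0.17) in lamina propria, with 11 of 15 members below 0 in each, and C1qa was at 60.0 against 131 CPM in SILT, whereas the macrophage marker Cd163 was 2.34-fold (1.85 to 2.96) and 1.42-fold (1.24 to 1.63) higher. Cells of the Retnla cluster held 513 CPM of Ear2 and 19146 CPM of Retnla in wild-type SILT, and the type 2 cells there held 8.10 CPM of Retnla.

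Itgae, which encodes CD103, was lower in Csf2-/- dendritic cells of both kinds. In type 1 dendritic cell-like cells it was 8.54-fold lower in SILT (5.49 to 13.97) and 4.28-fold lower in lamina propria (2.62 to 7.14), although it is a marker of that class. In type 2 cells it was 3.55-fold lower in SILT (2.39 to 5.45), and in lamina propria 0 UMIs stood against 63. Of the 11 wild-type SILT cells with a Csf2 UMI, 9 lay in cluster 18, and of these 7 held Il7r, 7 Cxcr6, 4 Kit, 3 Il22 and 1 Cd3e. Of the other 133 cells of cluster 18, 77 held Il7r, 31 Cxcr6, 24 Kit, 1 Il22 and 68 Cd3e.

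The Il22ra2 clusters held a smaller share of Csf2-/- than of wild-type SILT cells, 6.33% against 14.6%. Clusters drawn from genes that differ between the libraries are argued against, since the shares were 6.88% (5.90 to 7.98) and 15.1% (14.3 to 15.9) without the leading genes. Shallow droplets or free RNA are argued against as the whole cause, since among cells with at least 3000 UMIs the shares were 0.549% (0.264 to 1.01) and 1.84% (1.5 to 2.24). Those shares rest on 10 of 150 Csf2-/- and 99 of 1105 wild-type cells of the clusters and do not cover the shallow majority. A smaller amount of lymphoid tissue in the Csf2-/- preparation may account for it: among these cells and B cell-like cells together the clusters held 60.7% (54.3 to 66.9) in Csf2-/- and 66.8% (64.4 to 69.0) in wild type, with overlapping intervals. An effect of CSF2 on these cells stays open and untested.

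The Retnla cluster was smaller in both Csf2-/- libraries. Among cells with at least 3000 UMIs the cluster held 0.477% (0.206 to 0.937) in Csf2-/- and 2.43% (1.95 to 2.98) in wild-type lamina propria, and 0.110% (0.0133 to 0.396) and 0.745% (0.533 to 1.01) in SILT. That test cannot decide on a difference in depth, because the cells of the cluster are deep, with a median of 13001 UMIs. In lamina propria 8 of its 10 Csf2-/- and 88 of its 91 wild-type cells passed the floor. In lamina propria cells joined by the leading genes of the cluster are argued against, since it held 0.356% (0.143 to 0.732) against 1.60% (1.25 to 2.02) when clustered without these genes. In SILT such a grouping may account for the difference, the intervals overlapping in the same test (0.211%, 0.0686 to 0.492, against 0.529%, 0.378 to 0.719). Cells with at least 3000 UMIs and 1000 CPM of Retnla were 0.655% (0.328 to 1.17) against 3.26% (2.70 to 3.89) in lamina propria and 0.494% (0.226 to 0.936) against 1.25% (0.968 to 1.58) in SILT, but this planned test decides nothing, because it falls with the level of the gene. Retnla was lower in other cells of Csf2-/- mice as well, in monocyte-like cells 10.8-fold (8.22 to 14.6) in lamina propria and 12.3-fold (9.11 to 17.1) in SILT. Within macrophage cluster 2 it was 1.92-fold and 1.32-fold lower, and in endothelial-like cells 16.7-fold and 2.25-fold. Monocyte-like cluster 3 held 9 and 5 wild-type cells above that Retnla gate and 1 and 1 in Csf2-/- (lamina propria and SILT). Macrophage cluster 2 held 32 and 13 such cells in wild type and 6 and 4 in Csf2-/-. A few such cells are therefore not excluded as a source of the ratio in either cluster. In the cells of the Retnla cluster itself the gene was 1.85-fold (1.71 to 2.01) lower in lamina propria, over 10 Csf2-/- cells. In SILT it was 3.41-fold (2.72 to 4.34) lower, over only 2 Csf2-/- cells. A lower level of the gene is therefore not separated from a loss of cells in SILT. Carry-over of serosal tissue cannot be told apart from an effect of the genotype, because the serosal genes Msln, Upk3b, Wt1 and Lrrn4 gave 1 UMI over all 4 libraries, too few for a comparison. An effect of CSF2 on these cells or on the gene stays open and untested.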
